A study of Mus musculus with 6 samples.

How the data were processed

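Gene expression was measured on Affymetrix arrays in MLE-15 cells, a mouse lung epithelial line immortalised with the SV40 large T antigen. The 6 samples were 3 control arrays and 3 arrays of cells given PMA (phorbol 12-myristate 13-acetate, a phorbol ester that activates protein kinase C). The dose of 10 nM and the exposure of 24 h were taken from the series design text, since the sample labels name only the treatment. Human cells that the same text mentions were not analysed here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

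Per the labels' protocols, RNA was extracted with Trizol and biotinylated cRNA was made from 0.5 µg of total RNA. The deposited values are on the log2 scale, and per the submitters' processing notes they were made with RMA, which corrects background, quantile-normalizes the arrays and summarises the probes of each probe set. The version of RMA, the name of the array, the scanner, the annotation and any filter are not given in the sources used here. RMA brings the arrays to a common distribution, so a shift of all transcripts in one direction would not be visible in these values. The values were used as deposited, with no further background correction or normalization in the analysis reported first. Array medians ran from 5.64 to 5.71, and the number of arrays limits the precision.

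The table held 1246 probe sets. Of these, 963 were named through the RefSeq accession in the probe set's own name, matched without versions to the RefSeq gene table of mouse assembly GRCm38.p6, and they covered 909 genes. The other 283 stayed unnamed. No genome build is named for the array, so no coordinates are given. For the 48 genes with several probe sets, the one with the highest mean value stood for the gene. Some probe sets can bind several transcripts, as marked by the suffix s in 237 and x in 38. The table held no background or control probe sets, so no gene was called present or absent, and values of different probe sets do not rank transcripts.

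PMA and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the 1246 probe sets and a threshold of 0.05 on the adjusted p. Each error given as SE is limma's moderated standard error. Lists of genes were tested with camera at a correlation of 0.01, again with the correlation estimated from each list, and with fry, on 1 value per gene. Of 19 lists, 17 had the 3 or more measured genes that the tests were given. Single-gene results were also adjusted over the list alone.

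The design, the lists, the alternatives and the rule for naming genes were set before the data were examined. That rule took the 12 largest rises and the 12 largest falls among genes that passed and whose groups did not overlap. It took every sialyltransferase, sulfotransferase and mucin that passed, with the 2 others of largest absolute change in each of those lists. In every other list it took the 2 members of largest absolute change. Where fewer than 5 genes passed, it added the 10 genes with the smallest unadjusted p. Other genes are named as examples of their list, chosen after their values were seen.

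The groups share the replicate numbers 1, 2 and 3, and the sample titles carry matching names across the groups, with a letter for numbers 2 and 3 and none for number 1. The labels do not say what a shared number stands for. Whether the numbers pair the arrays was checked by correlating, across probe sets, each array's deviation from its group mean. Arrays with the same number correlated at 0.956, 0.815 and 0.912, all over 0.1, the value set for treating the numbers as pairs. Because number 1 lies far from the rest, deviations from the group mean make numbers 2 and 3 alike, and control 2 correlated more closely with PMA 3 (0.886) than with PMA 2. With number 1 set aside, control 2 minus control 3 and PMA 2 minus PMA 3 correlated at 0.041 across probe sets, so the data set number 1 apart and show little pairing within numbers 2 and 3. A fit with the number as a block was therefore run beside the unblocked fit. The comparison of the number 1 arrays with the other arrays, with PMA as a term, the fit with 1 batch term for number 1, the correlation with number 1 set aside, and the test of whether the PMA difference depends on the number were added after seeing the data.

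The procedure was tested on simulated data built on these 1246 probe sets, with 200 of them changed by known amounts, 50 at each size. Without the block, 48% of probe sets changed by 0.58 log2 units and 80% of those changed by 1 were called. With the block, 72% of those changed by 0.26 and 100% of those changed by 0.58 were called, along with 9 unchanged probe sets. The adjustment is more lenient with 200 changed probe sets than with a few. These rates therefore do not carry over to data with few changes, where fewer would be called.

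Alternatives were median centring, a repeated quantile normalization, cyclic loess, leaving out the dimmest probe sets, a trended and robust variance, a minimum change of 1.5-fold, the mean of a gene's probe sets, the block, leaving out each array, and leaving out number 1 in both groups.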

Results

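The series measured RNA from cultured MLE-15 mouse lung epithelial cells on 6 arrays, 3 from control cells and 3 from cells exposed to 10 nM PMA for 24 h. It asked whether sialyltransferases, which add sialic acid to glycans, sulfotransferases, which add sulfate, and mucins are expressed and are induced by PMA. Levels are RMA values on the log2 scale, given as mean ± SD with n = 3 arrays per group. Medians of the arrays lay between 5.64 and 5.71. The table covered 909 named genes, among them 19 of 20 listed sialyltransferases, 33 of 36 sulfotransferases and 11 of 21 mucins. Muc2, Muc6 and Muc16 were among the listed genes without a probe set named here.

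Among the sialyltransferases, St8sia6, which adds sialic acid in α2,8 linkage, had a mean of 8.71 ± 0.11 in control and 8.98 ± 0.19 in PMA arrays. The difference was 0.28 log2 units (SE 0.12), and the 3 pairs gave 0.29, 0.51 and 0.039. All 3 pairs had the same sign in 23.1% of all probe sets, against 25% by chance. St3gal1, an α2,3-sialyltransferase acting on mucin-type O-glycans, stood at 8.88 ± 0.75 and 9.10 ± 0.66, a difference of 0.21 (SE 0.50). St8sia2, a polysialyltransferase, stood at 5.11 ± 1.02 and 5.29 ± 1.12. St6gal1, the α2,6-sialyltransferase of N-glycans, stood at 8.95 ± 1.38 and 8.97 ± 1.20. None of these differences passed the test. Of the 19 sialyltransferases, 15 had a higher and 4 a lower mean with PMA, with a median difference of 0.067 log2 units. By limma with Benjamini-Hochberg adjustment, 0 of the 19 passed over all probe sets and 0 when adjusted over the list alone, with 0 at an unadjusted p under 0.05. With the replicate number as a block limma again called 0, with 2 at an unadjusted p under 0.05, St8sia6 (unadjusted p = 0.0139) and St8sia2 (unadjusted p = 0.0260). As a list they had an adjusted p = 0.393 by camera (unadjusted p = 0.0463) and an adjusted p = 0.992 with an estimated correlation. In fits that keep the numbers balanced between the groups, the camera adjusted p was 0.116 with the block (unadjusted 0.00680). With an estimated correlation it was 0.976. That estimate was 0.0047, under the 0.01 set for the first test, so correlation between the genes does not account for the rise. With number 1 left out of both groups the camera adjusted p was 0.102 (unadjusted 0.00602, median difference 0.086), and 0.857 with an estimated correlation. Leaving out 1 array unbalances the numbers, and the median difference was then 0.157 without control 1, 0.123 without PMA 2 and 0.134 without PMA 3, but negative without control 2 (-0.0079), control 3 (-0.046) or PMA 1 (-0.039).

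Among the sulfotransferases, Chst7, which sulfates chondroitin and N-acetylglucosamine residues, had a mean of 4.70 ± 0.37 in control and 4.52 ± 0.30 in PMA arrays. The difference was -0.18 log2 units (SE 0.24), and the 3 pairs gave -0.26, -0.14 and -0.15. Hs3st1, a heparan sulfate 3-O-sulfotransferase, stood at 7.99 ± 0.53 and 7.83 ± 0.77, a difference of -0.16 (SE 0.46). Tpst2, which sulfates protein tyrosines, stood at 9.51 ± 0.34 and 9.49 ± 0.44. Ndst1, which starts the sulfation of heparan sulfate, stood at 9.15 ± 0.61 and 9.25 ± 0.54. Of the 33 measured members, 15 had a higher and 18 a lower mean with PMA, and the median difference was -0.0092. By limma with Benjamini-Hochberg adjustment, 0 of the 33 passed, 0 when adjusted over the list alone, and 0 had an unadjusted p under 0.05. With the block limma again called 0, with 1, Chst7, at an unadjusted p under 0.05. The list as a whole had an adjusted p = 0.992 by camera.

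Among the mucins, the secreted gel-forming mucin Muc5ac stood at 7.70 ± 1.76 in control and 7.88 ± 1.25 in PMA arrays, a difference of 0.18 log2 units (SE 1.06). The 3 pairs gave Muc5ac differences of 0.78, -0.35 and 0.094, and its mean difference was -0.13 with number 1 left out of both groups. Muc5b, the other gel-forming mucin measured, stood at 10.68 ± 0.64 and 10.74 ± 0.67. Cd164, a sialomucin of the cell surface, stood at 10.55 ± 0.53 and 10.69 ± 0.50, a difference of 0.14 (SE 0.36). The transmembrane mucin Muc1 stood at 5.55 ± 0.26 and 5.53 ± 0.14. Muc4 had 3 probe sets, with differences of -0.033, 0.025 and 0.070. Of the 11 mucins, 7 had a higher and 4 a lower mean with PMA, with a median difference of 0.019. By limma with Benjamini-Hochberg adjustment, 0 of the 11 passed, 0 when adjusted over the list alone, and 0 had an unadjusted p under 0.05, each also with the block. By camera the list had an adjusted p = 0.992, with a direction of down against a median and mean above 0.

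**Figure D1:**
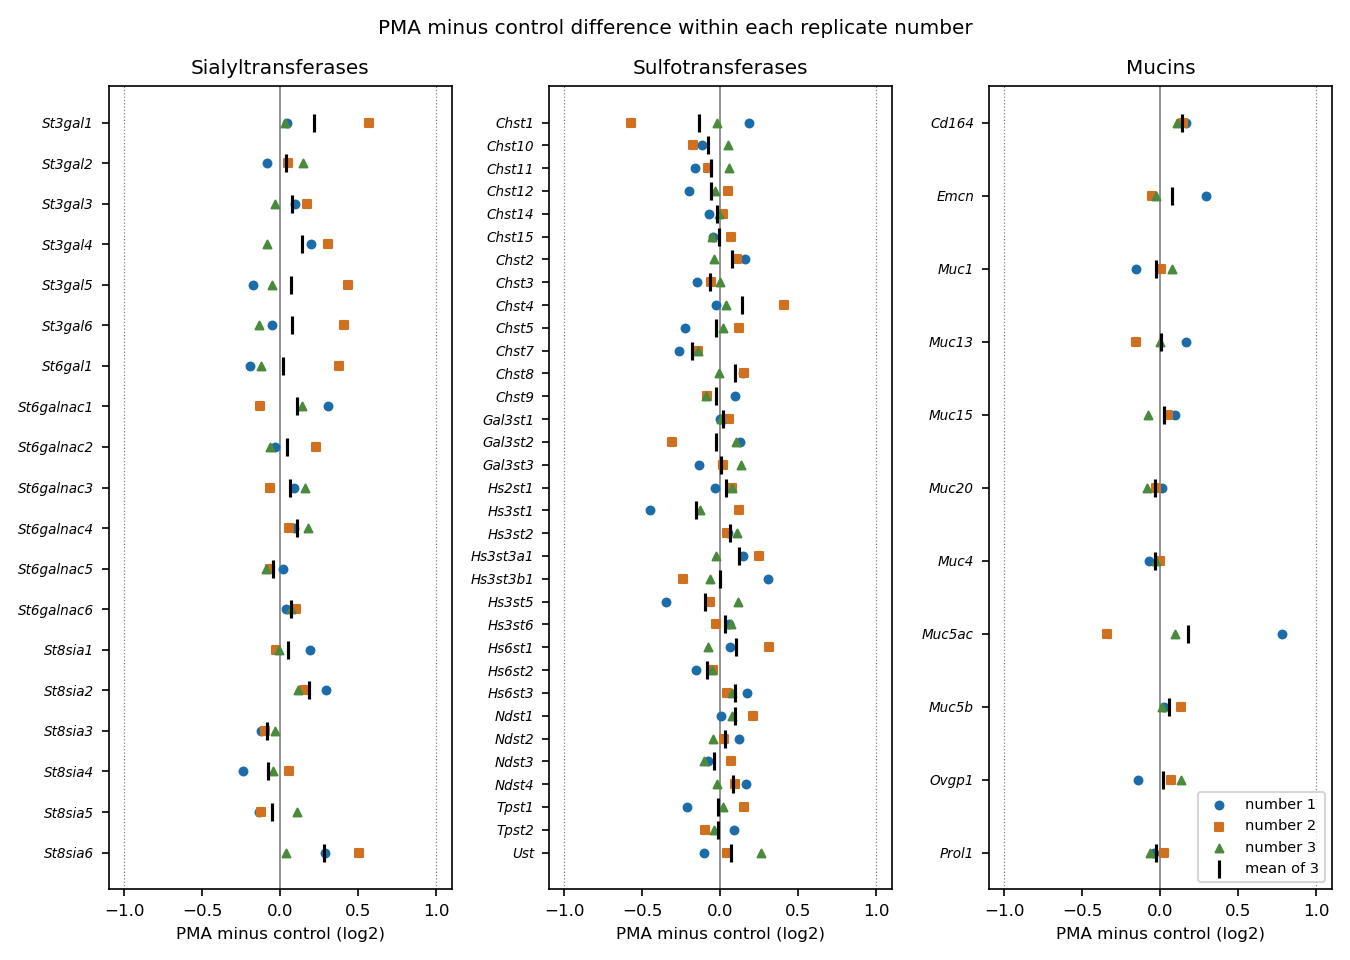
Difference between the PMA and the control array of the same replicate number (log2 units, horizontal axis) for each measured sialyltransferase, sulfotransferase and mucin (vertical axis), with a bar at the mean of the 3 differences. All 63 genes lie within 1 log2 unit in each pair, and Muc5ac in number 1, at 0.78, lies farthest from 0.

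Over all 1246 probe sets, limma with Benjamini-Hochberg adjustment called 0 as changed by PMA, with 4 at an unadjusted p under 0.05. The smallest adjusted p was 0.999. An even spread of p-values would give 62.3, but the spread between the numbers widens the error of this fit. Other groupings of the arrays that also part each pair gave 3 to 12. With the replicate number as a block, limma called 0, with 42 at an unadjusted p under 0.05 and a smallest adjusted p of 0.992. The largest absolute difference of any probe set was 0.44 log2 units and the median absolute difference was 0.050. In the blocked fit the 95% interval of the difference lay within 1 log2 unit of 0 for all 1246 probe sets and within 0.58 for 1242, including all 63 sialyltransferases, sulfotransferases and mucins. With 1 term for number 1 in place of the block, which pairs nothing within numbers 2 and 3, the counts were 1246, 1241 and 63. In the unblocked fit 1104 intervals, and 49 of those 63, lay within 1 log2 unit.

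The genes with the smallest unadjusted p did not pass the adjustment either. Mrpl52, a protein of the mitochondrial ribosome, stood at 10.16 ± 0.024 in control and 9.94 ± 0.11 in PMA arrays, a difference of -0.21 log2 units (SE 0.076). Siglech, a Siglec family receptor of plasmacytoid dendritic cells, differed by -0.15 (SE 0.061), but its 3 probe sets disagreed in sign, at -0.15, -0.0023 and 0.067, with a mean of -0.030. Ptch1, the Hedgehog receptor, differed by 0.15 (SE 0.069), and B3galt1, a galactosyltransferase, by 0.14 (SE 0.061). B4galnt3 differed by -0.14, Cks1b, a cell cycle regulator, by -0.14, Pgm5 by 0.19, Cox18 by -0.17 and the O-glycan initiating enzyme Galnt9 by -0.12. Siglech, B3galt1 and Pgm5 had group means of 3.43 to 3.77, below the lower quartile of every array (4.32 to 4.43). The probe sets of Siglech and B3galt1 also carry the suffix x.

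The other glycan lists gave differences of similar size, and 0 of their genes passed by limma, with 0 at an unadjusted p under 0.05. With the block limma again called 0. An unadjusted p under 0.05 was then met by 3 genes of glycosaminoglycan chain synthesis, 2 proteoglycans and 1 gene of N-glycan branching and galactosylation. Sult1e1 and Sult1a1 led the 6 cytosolic sulfotransferases, which act on small molecules (1 higher, 5 lower), at -0.049 and 0.038. The 24 enzymes of mucin-type O-glycans (16 higher, 8 lower) were led by B3gnt3 at -0.17 and Galnt10 at 0.16. The 10 fucosyltransferases (5 higher, 5 lower) were led by Pofut1 at 0.10 and Fut8 at 0.097. The 21 enzymes of N-glycan branching and galactosylation (9 higher, 12 lower) were led by Gcnt2 at 0.17 and Man2a2 at -0.13. Csgalnact1 at 0.21 and Chsy3 at 0.20 led the 19 genes of glycosaminoglycan chain synthesis (12 higher, 7 lower). Cd44, the hyaluronan receptor, at 0.23 (SE 0.12) and Vcan at 0.20 led the 24 proteoglycans (15 higher, 9 lower). Nans at -0.11 and Cmas at -0.098 led the 9 genes of sialic acid metabolism (5 higher, 4 lower). Arsb at 0.14 and Arsa at 0.11 led the 9 genes of sulfate donors and sulfatases (5 higher, 4 lower). Lgals4 at -0.13 and Lgals3 at -0.12 led the 8 galectins (3 higher, 5 lower).

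Signalling and marker lists were measured too, again with 0 genes passing by limma and 1, Siglech, at an unadjusted p under 0.05. With the block limma again called 0, with Mrc1, Siglech, Fgf2 and Junb at an unadjusted p under 0.05. The 26 chemokines and cytokines (17 higher, 9 lower; camera adjusted p = 0.361, unadjusted 0.0213; adjusted p = 0.992 with an estimated correlation) were led by the neutrophil chemokine Cxcl1 at 0.21 and Il1b at 0.20. Fgf2 at -0.19 and Vegfa at 0.16 led the 25 growth factors (13 higher, 12 lower), and Notch4 at 0.14 and Hes1 at 0.097 led the 14 genes of the Notch pathway (7 higher, 7 lower). Of 23 listed phorbol ester response genes only Junb, at -0.16 (SE 0.37), and Icam1, at 0.15 (SE 0.33), were measured. Of 13 lung epithelial markers only the surfactant proteins Sftpd, at -0.042, and Sftpa1, at -0.032, were measured. Among markers of other cells, the mannose receptor Mrc1 differed by 0.38 (SE 1.11), Vcam1 by 0.13 and Sele by -0.026, in lists of 16 leukocyte markers (11 higher, 5 lower) and 4 endothelial and fibroblast markers (2 higher, 2 lower). Of the 17 lists tested by camera, 0 passed the Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05. By fry, which asks whether a list's genes move one way on balance, 0 passed, with a smallest adjusted p of 0.981 and 0 at an unadjusted p under 0.05. Besides the mucins, mean, median and camera differed in sign in 4 lists, each with a camera direction of down. Mean and median were above 0 for the proteoglycans and for sulfate donors and sulfatases, only the median (0.0033) for the growth factors and only the mean (0.0029) for N-glycan branching and galactosylation.

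The array pair with replicate number 1 stood apart from the other 4 arrays in both groups, and some sialyltransferases, sulfotransferases and mucins differed with it. St6galnac2, which sialylates O-glycans, averaged 8.31 in the 2 number 1 arrays and 5.49 in the 4 arrays of numbers 2 and 3, a difference of 2.82 log2 units (SE 0.078). Muc5ac was lower in number 1, at 6.06 against 8.65, a difference of -2.59 (SE 0.17). Ust, the uronyl 2-O-sulfotransferase, averaged 9.96 and 8.25, a difference of 1.71 (SE 0.089). By limma with Benjamini-Hochberg adjustment and PMA as a term, the adjusted p was 1.35e-09 for St6galnac2 and 6.16e-07 for Muc5ac.

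In that comparison, chosen after seeing the data, 41.7% of all probe sets were called. Of the 19 sialyltransferases 9 were higher in number 1 and 0 lower. They included St6gal1 at 2.22 (SE 0.11), St8sia2 at 1.85, St3gal5, the GM3 synthase, at 1.79 and St3gal1 at 1.17. Of the 33 sulfotransferases 16 were higher, among them Chst2 at 1.47 and Ndst1 at 0.98, and 4 were lower, among them Hs3st1 at -1.11 and Chst4 at -0.59. Of the 11 mucins 2 were higher, Ovgp1 at 0.74 and Muc1 at 0.33, and 3 were lower, Muc5ac, Muc5b at -1.13 and Cd164 at -0.85. Adjusted over the list alone, the counts were 9, 20 and 5. By camera none of the 3 lists passed, with adjusted p = 0.122, 0.359 and 0.409, and with an estimated correlation the adjusted p = 0.785 for each. By fry, which does not compare a list with other genes, they had an adjusted p of 0.00211 (up), 0.00229 (up) and 0.0164 (down). Passing fry was not particular to them. Most of the other lists passed fry too, such as the growth factors (adjusted p = 0.00192), and the rest did not, such as the galectins (adjusted p = 0.643).

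Over all probe sets, 519 of 1246 differed between number 1 and the other arrays by limma with Benjamini-Hochberg adjustment, 343 higher and 176 lower. In number 1 the largest differences upward among named genes were in Ugt1a6b, a glucuronosyltransferase, at 3.57, Il17rd at 2.98, the TGF-β co-receptor Tgfbr3 at 2.98 and the proteoglycan Cspg4 at 2.90. The largest downward among named genes were in the chemokine receptor Ccr7 at -3.22, Wnt5a at -3.20 and the galectin Lgals4 at -3.15. Next came the chemokines Ccl20 at -3.09 and Cxcl2 at -3.06, and the unnamed probe set uc009abs.1_psr1_at differed by -4.41. The probe sets of Ugt1a6b, Wnt5a, Lgals4 and Ccl20 carry the suffix s, so they can bind several transcripts. The difference measured in control arrays and that measured in PMA arrays correlated across probe sets at r = 0.956, though probe sets are not independent replicates. Between 110 and 125 probe sets differed by more than 2-fold between a number 1 array and any array of number 2 or 3, against 1 between control 1 and PMA 1 and 0 among the other 4 arrays. The number stands for 1 pair against 2 pairs, so these p-values compare these arrays only.

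**Figure D2:**
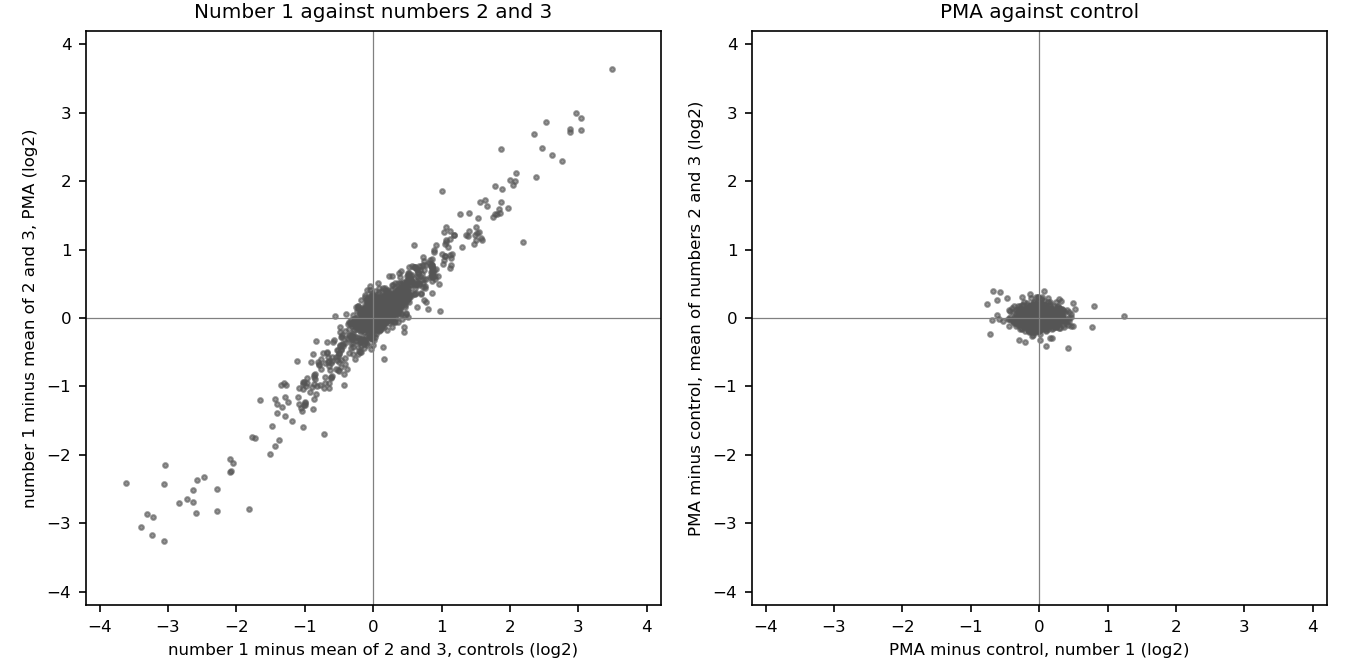
Each point is a probe set. The left panel plots number 1 minus the mean of numbers 2 and 3 in control (horizontal axis) and in PMA arrays (vertical axis), and the right panel plots PMA minus control in number 1 and in numbers 2 and 3, all in log2 units. The left panel follows a line with r = 0.956, while in the right panel 1 probe set, uc009kma.1_psr1_at at 1.24 in number 1, differs by more than 1 log2 unit and Mrc1 and Muc5ac reach 0.80 and 0.78 in number 1.

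**Figure D3:**
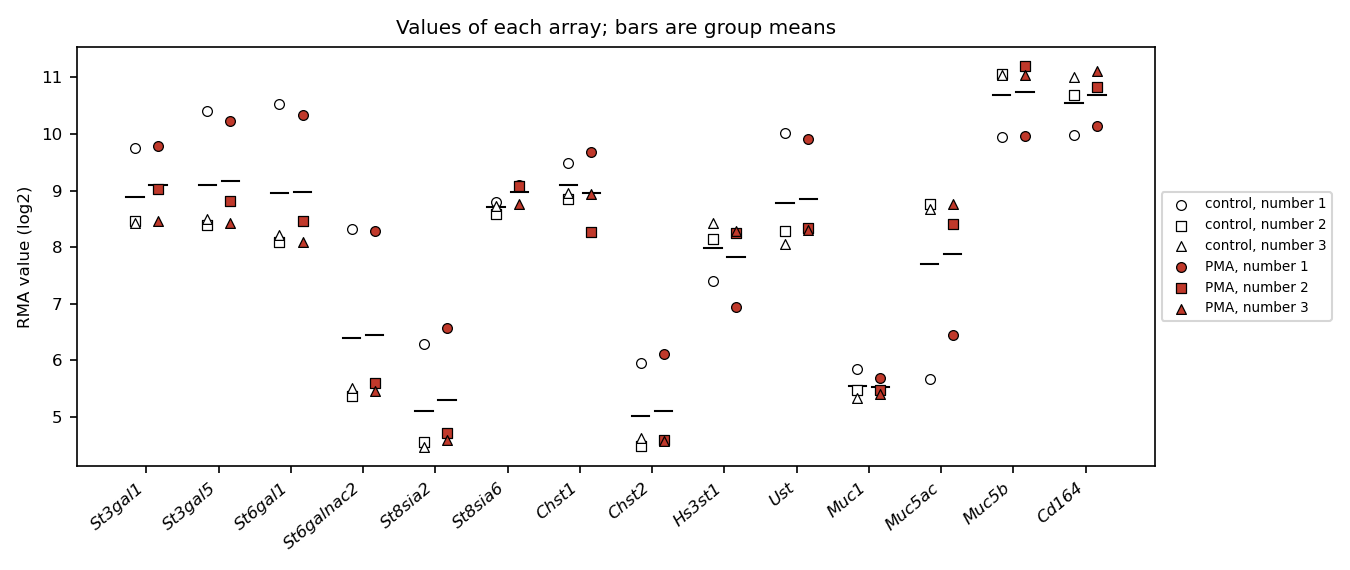
RMA values (log2, vertical axis) of 14 sialyltransferases, sulfotransferases and mucins on each of the 6 arrays, with a bar at each group's mean, open symbols for control and filled symbols for PMA. Circles, the number 1 arrays, lie apart from the other symbols of both groups for St6galnac2, St6gal1, Ust and Muc5ac.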

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

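Of the tests in this part, those of the spread between numbers, of 1 poor array, of added cells and of mixed RNA were chosen only after the result was seen.

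The absence of PMA calls was the first pattern weighed. With the number as a block, which removes the spread between numbers, 0 probe sets passed by limma (42 at an unadjusted p under 0.05). Exchanging the labels within 1 number gave 0 at most (38 to 78 unadjusted). Both argue against large changes hidden by the spread between numbers or by a swap inside 1 pair. A swap with smaller changes cannot be told from 0 calls. The 78 came from exchanging number 2, and exchanging number 1 took limma's smallest adjusted p from 0.992 to 0.125. The blocked 95% interval excluded a doubling of the measured signal for 100% of probe sets, so in that fit the arrays were not too few to show one. In the unblocked fit 1104 of the 1246 intervals excluded it. Both counts cover these arrays only, since the labels do not say that the replicates came from separate cultures. Signal over background is unknown, so a doubling of a transcript with a dim probe set may not be excluded. The differences of the 3 numbers correlated across probe sets at -0.078, -0.107 and 0.0772 at most, and since probe sets are not independent the error of these values is not known well enough to place them under the bound of 0.1 that had been set, so small changes shared by the numbers may still be present. A count of 0 is met by every split of the arrays by construction, so the 10 splits decide nothing here. The highest other split, control 1, PMA 1 and PMA 2 against the rest, gave 1 call. Only 2 of the 23 listed phorbol ester response genes were measured, and neither passed by limma. Whether PMA acted on the cells at all therefore cannot be told from these values.

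The distance of the number 1 arrays from the rest was the second pattern. It was defined on both number 1 arrays, whose differences correlated at 0.956, so 1 poor array is ruled out by that definition and not by a separate test. A loess curve on the mean value explained 0.679% of the variance of the difference, so little of it follows intensity in the deposited values. RMA had already quantile-normalized the arrays, so this share cannot tell whether the raw values held such a bias. A small share of other cells added to the same cells would lower the original transcripts little and alike. Yet 48 probe sets were lower by over 1 log2 unit in number 1 of both groups, which argues against a small share only. The median over the brightest part of the probe sets moved by 0.15, but RMA brings the arrays to a common distribution, so it decides little. A large share of other cells in number 1, or other cells in numbers 2 and 3, was not tested and stays open. A different passage, stock or culture of the line, or a separate processing batch, may also lie behind the distance of the number 1 arrays. The sample titles of number 1 are written differently from those of numbers 2 and 3 in both groups, without a letter, but no label says what this marks, so batch and culture stay open and neither was tested.

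The unnamed probe set uc009kma.1_psr1_at was singled out because its PMA difference in number 1 exceeded that in numbers 2 and 3 by 1.21 log2 units (limma interaction with Benjamini-Hochberg adjustment, adjusted p = 0.0360). It was the only one of 1246 probe sets to pass, with 70 at an unadjusted p under 0.05. It read 4.61 in control 1 and 5.85 in PMA 1, against 8.21 to 8.31 on the other arrays. RNA of numbers 2 or 3 mixed into PMA 1 would raise most probe sets that are lower in number 1, but 42.9% of them (24 of 56) were higher in PMA 1 than in control 1, which argues against it. With 1 pair behind number 1 the difference has no replicate, and its origin stays open.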

How the results depend on the processing

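The fits that add a term for number 1, the interaction and all results on number 1 were chosen after seeing the data. The count of probe sets changed by PMA, and the counts among sialyltransferases, sulfotransferases and mucins, were 0 by limma under every alternative run, with 0 to 44 probe sets at an unadjusted p under 0.05. The replicate block gave 0 and changed no other call, and with number 1 left out of both groups the count was 0 (17 unadjusted). The list tests gave 0 calls except without the dimmer part of the probe sets, where 1 list, the sialyltransferases, passed camera (12 genes, adjusted p = 0.0314). The call was lost with an estimated correlation (adjusted p = 0.935), and the cause was not tested. The smallest adjusted p of any list, by camera or fry, ran from 0.0314 to 0.992 across alternatives, the highest with an estimated correlation. The number 1 comparison called 403 to 543 of 1246 probe sets, and 380 of 623 without the dimmer part and 442 of 831 without the dimmest. Control probe sets could not be kept because the table held none, and the alternatives for expressed genes were not run for want of background probe sets; for the same reason signal over background is unknown.

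None of the 46 named genes passed under any of 712 alternative values, and 13 kept their sign throughout, though 7 of these moved by over 1.5 times. With number 1 left out of both groups Il1b came to 0.059, Vegfa to 0.087 and B4galnt3 to -0.087, and with the mean of its probe sets Siglech came to -0.030. Without control 1 Il1b came to 0.11 and Vegfa to 0.025, without control 2 Cd44 to 0.12, without control 3 Vegfa to 0.30, and without PMA 2 Cox18 to -0.11 and Pgm5 to 0.12. With number 1 left out of both groups Muc5ac came to -0.13 and Notch4 to -0.0029, because their positive means rested on the number 1 pair. That pair gave 0.78 for Muc5ac and 0.43 for Notch4, and why it differed from the others was not tested. The other reversals came from leaving out 1 array, which by construction leaves the replicate numbers unbalanced between the groups. The lowest and highest log2 differences without 1 array were, for the genes concerned, Arsa (-0.31 to 0.62), Arsb (-0.035 to 0.38), B3gnt3 (-0.64 to 0.30), Cd164 (-0.15 to 0.42), Chst7 (-0.36 to 0.030), Chsy3 (-0.29 to 0.72), Cmas (-0.46 to 0.24), Csgalnact1 (-0.13 to 0.52), Cxcl1 (-0.21 to 0.54), Fgf2 (-0.35 to 0.0085), Fut8 (-0.24 to 0.42), Galnt10 (-0.26 to 0.62), Gcnt2 (-0.037 to 0.39), Hes1 (-0.0030 to 0.19), Hs3st1 (-0.45 to 0.29), Icam1 (-0.058 to 0.44), Junb (-0.45 to 0.16), Lgals3 (-0.47 to 0.19), Lgals4 (-1.15 to 0.95), Man2a2 (-0.30 to 0.019), Mrc1 (-0.64 to 1.19), Muc5ac (-0.84 to 0.89), Nans (-0.21 to 0.046), Notch4 (-0.028 to 0.25), Pofut1 (-0.041 to 0.31), Sele (-0.46 to 0.29), Sftpa1 (-0.19 to 0.15), Sftpd (-0.11 to 0.0035), St3gal1 (-0.13 to 0.65), Sult1a1 (-0.080 to 0.15), Sult1e1 (-0.10 to 0.018), Vcam1 (-0.22 to 0.66), Vcan (-0.22 to 0.54).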

Other observations

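Members of further lists differed between number 1 and the other 4 arrays, by limma with Benjamini-Hochberg adjustment in the comparison chosen after seeing the data, in which 41.7% of all probe sets were called. Among the 14 genes of the Notch pathway 7 were higher and 1 lower in number 1, with the receptors Notch2 at 1.67 and Notch1 at 1.33 log2 units and the ligand Jag1 at -2.08. Among the 26 chemokines and cytokines 7 were higher, led by Csf2 at 2.17 and Il18 at 1.78, and 5 lower, led by Ccl20 and Cxcl2. Of the 24 proteoglycans 9 were higher and 2 lower, Acan at -2.57 and Dcn at -2.31. By camera 0 of the 17 lists passed, with 2 at an unadjusted p under 0.05.

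In glycosaminoglycan synthesis, Ext1, which extends heparan sulfate, was higher in number 1 by 2.01 log2 units (SE 0.066), while the chondroitin synthase Chsy3 was lower, at -1.53. Cmah, which makes N-glycolylneuraminic acid, was higher by 2.03, and Cmas, which activates sialic acid, differed by -1.06. Of the 4 measured endothelial and fibroblast markers, Pecam1 at -1.37, Vcam1 at -1.31 and Sele at -1.13 were lower and Selp at 0.39 was higher. Of the 16 leukocyte markers 1, Mrc1 at -2.74, was called lower and 1 was called higher.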
